A study of Mus musculus with 22 samples.

How the data were processed

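The series holds RNA-seq of 22 libraries of mouse liver cells labelled HSC, from 10 control and 12 diet samples at 4 zeitgeber times. Per the labels' protocols, RNA was extracted with a Promega kit and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were aligned with STAR 2.7.9a to GRCm38 (mm10), counted with HTSeq and normalised with DESeq2. How the cells were isolated, the annotation, the strand setting and the library batches are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. The deposited count table gives whole-number read counts for 55367 gene symbols, and no entry lacks a gene name. The deposited normalised signal equals those counts divided by 1 DESeq2 size factor per library, per the values: 100% of its entries came back as whole reads within 0.001 and 100% of these equal the count table, so a count test on them calls the same 11748 genes. Groups were taken from the sample titles, and each table column was matched to its sample by the description in the labels. The labels give an age of 20 weeks, a start of the diet at 8 weeks and 12 weeks of diet, while another field gives 6 months.

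Counts per gene were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the 8 groups (22409 kept), libraries were scaled by TMM, and glmQLFit and glmQLFTest were run on 1 model with a mean for each of the 8 groups. All groups share 1 estimate of the spread because 2 control groups hold 2 libraries. Contrasts were the mean of the 4 diet minus control differences, the difference at each time, F tests over the 4 times in control and under diet, and the F test of the diet by time interaction. Genes at a Benjamini-Hochberg adjusted p under 0.05 are called changed. Fold changes are log2 with their standard errors, and CPM values are means ± SD over libraries. Log2 CPM used a prior count of 2.

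Gene lists were tested with camera at a preset correlation of 0.01 between genes, again with the correlation estimated per list, and with fry, adjusted over the 35 lists. For the F tests the number of called members was compared with all other tested genes by Fisher's exact test, adjusted over the lists; it treats genes as independent, so its p is too small where members move together. Some genes stand in more than 1 list. The clock amplitude is the mean over the clock list of the amplitude of a 24 h cosine fitted to log2 CPM, compared by an exact permutation of the diet labels within each time (40000 arrangements).

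The test design, the 35 lists, the rule for the genes named and most alternatives were fixed before the data were examined. The rule names the 8 higher and 8 lower genes with the largest log2 change over all times, the 3 higher and 3 lower at each time, and the 8 with the smallest p in each F test. All of these must be called, have a mean log2 CPM of at least 2 and a symbol that is not a placeholder or pseudogene, and those over all times must have the same sign at each time. It also names every measured clock gene, a set of 20 anchor genes of fibrosis and cell identity, and up to 4 members of each list with the smallest p. The anchor Tagln did not pass the filter on low counts. The text leaves out 4 genes that the rule names. Of the gene symbols, 53292 were found in the GENCODE M21 annotation of GRCm38, 53186 of them at 1 place; coordinates are 1-based and come from it.

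Diet over all times, diet at ZT6, times in control, times under diet and the interaction were tested on simulated data. These were drawn from the means and library sizes of these samples with 200 genes changed. Diet at ZT0, ZT12 and ZT18 was not simulated. The changed genes had a mean over 4 CPM, so recovery of rarer genes was not measured. The test recovered 92.5% of 2-fold changes over all times, and, of 4-fold changes, 89% at ZT6, 92% between times in control, 88.5% under diet and 65% of those in the interaction. In these, 3.65%, 3.26%, 2.65%, 5.35% and 6.47% of calls were false. The real libraries gave 11748 genes changed by diet over all times and 6752 at ZT6, far more than the 200 simulated. Recovery, false calls and the scaling with so many changed genes were thus not measured. Each pair of replicates differed by far more than sampling noise (chi-square per degree of freedom of 17.5 or more), so no library was counted as a repeat.

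Alternatives were other scalings (RLE, library size only), no filter or a mean CPM of at least 5, DESeq2 1.42.0, a replicate block, a hepatocyte score as covariate, 24 h cosine terms, only the groups compared, a prior count of 0.5 for the amplitude and each library left out in turn. Added after the data were seen were leaving out 2 control libraries that stand apart (replicate 2 of ZT0 and replicate 1 of ZT18), leaving out each time, and an endothelial score as covariate. Also added were 7 marker lists for T cells, NK cells, B and plasma cells, T cell checkpoints, sinusoidal and all endothelium, and core stellate cells. Figures were drawn with matplotlib.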

Results

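RNA was sequenced in 22 libraries of mouse liver cells that the labels call HSC, the usual abbreviation of hepatic stellate cells, which store retinoids and make scar matrix. The 10 control libraries came from mice on chow. The other 12 came from mice on CDA-HFD, a choline-deficient, amino acid-defined high-fat diet used to model steatohepatitis with fibrosis. Mice were killed at zeitgeber time (ZT) 0, 6, 12 or 18 h, with ZT0 at lights on and ZT12 at lights off. Control groups held 3 libraries at ZT0, 2 at ZT6, 2 at ZT12 and 3 at ZT18, and each of the 4 diet groups held 3. Each library held 19754805 to 41665623 counts in genes, and 22409 of the 55367 listed genes were tested. One field of the labels gives 12 weeks of diet and another 6 months, so the length of the diet is not settled. No label says that each library came from its own animal, so p-values measure the spread between these libraries, which may be technical. The first principal component held 40.2% of the variance and parted all 10 control libraries from all 12 diet libraries. Replicate 2 of control ZT0 lay nearer to the diet libraries on it (-46.6) than any other control library, and replicate 1 of control ZT18 stood apart on the second component (-110.1).

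The title of the series names a steatohepatitis model and daily time in these cells, so the first comparison is diet against control over all 4 times. Endothelial genes were lower in the diet libraries, and most measured genes of lymphocytes, neutrophils and dendritic cells, and antigen presentation were higher, though of these lists only the endothelial one was called with an estimated correlation. Kdr, the main receptor of vascular endothelial growth factor (chromosome 5, 75932827 to 75978458 on GRCm38), fell from 2959.8 ± 501 counts scaled to library size (CPM; SD, n = 10) to 132 ± 40.9 CPM (n = 12), a log2 change of -4.55 ± 0.11 (SE). All 28 measured endothelial markers fell (28 when adjusted over the list alone), with a median log2 change of -3.98, adjusted p = 4.01e-76 and adjusted p = 0.00825 with an estimated correlation. Among them, Flt4, a receptor of lymphatic and sinusoidal vessels, fell by 4.08 on the log2 scale, Ptprb, an endothelial phosphatase, by 4.25, and the scavenger receptor Stab1 by 4.37. Pecam1, an adhesion molecule of vessel walls, fell from 977 ± 207 to 148 ± 31.9 CPM. In the control libraries Kdr and Stab1 (3218 CPM) were far more abundant than any stellate cell marker described below.

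Matrix genes moved with the endothelial genes. Of 28 collagens and structural matrix genes, 17 fell and 3 rose (20 called when adjusted over the list alone). As a list they were lower (adjusted p = 0.00022; adjusted p = 0.312 with an estimated correlation). Sparc, a collagen-binding matrix protein, fell from 2505 ± 685 to 293 ± 53.8 CPM (log2 -3.10 ± 0.09). The proteoglycan Bgn changed by -3.35 ± 0.12 and the basement membrane collagen Col4a1 by -3.30 ± 0.13. Among 28 genes of matrix cross-linking and turnover, 17 fell and 3 rose (21 called when adjusted over the list alone). That list was lower too (adjusted p = 5.09e-05; adjusted p = 0.188 with an estimated correlation). Timp3, an inhibitor of matrix proteases, fell from 1153 ± 334 to 77.6 ± 20.4 CPM. Plod1, a collagen lysyl hydroxylase, changed by -2.88 ± 0.09 and the membrane protease Mmp14 by -2.32 ± 0.11. The macrophage elastase Mmp12 (chromosome 9, 7344381 to 7369499) rose from 1.80 ± 1.66 to 98.1 ± 40.9 CPM (6.04 ± 0.33). The endothelial list fell in the same libraries, and several genes named here are also made by endothelial cells.

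Some signalling lists were called lower with the preset correlation, and none with an estimated one. In the Hedgehog and Wnt list, 9 of 23 genes fell and 2 rose (11 called when adjusted over the list alone). The list was lower (adjusted p = 0.00929; adjusted p = 0.118 with an estimated correlation). Wnt2, a ligand made by central vein and sinusoidal endothelium, fell from 489 ± 152 to 22.001 ± 8.65 CPM, and the Wnt enhancer Rspo3 changed by -2.67 ± 0.19. Targets of YAP and TAZ had 10 of 18 genes lower and 5 higher (16 called when adjusted over the list alone; adjusted p = 0.00057; adjusted p = 0.225 with an estimated correlation). Among them were Amotl1 (-3.29 ± 0.11) and Wwtr1, which encodes TAZ (-2.45 ± 0.10). In the TGF-beta list, 14 genes rose and 14 fell of 32 (28 called when adjusted over the list alone). Its median was 0.04 and its mean -0.26, while the test gave it as lower (adjusted p = 0.0278; adjusted p = 0.225 with an estimated correlation). That call ended when any of 7 diet libraries was left out: replicates 2 and 3 of ZT0, 3 of ZT6, 2 and 3 of ZT12, and 1 and 3 of ZT18 (adjusted p from 0.0515 to 0.0579). It also ended with no filter on low counts (0.131) and at a mean CPM of at least 5 (0.0763). Ltbp4, which holds latent TGF-beta in the matrix, changed by -4.09 ± 0.11. The co-receptor Eng, abundant in endothelium, fell from 5994 ± 1289.6 to 372 ± 120.4 CPM. Lipid droplet and lipid uptake genes were called lower as a list (13 lower and 5 higher of 21, 18 called when adjusted over the list alone; adjusted p = 0.00868; adjusted p = 0.312 with an estimated correlation). So were glucocorticoid-induced genes (10 lower and 7 higher of 18, 17 called when adjusted over the list alone; adjusted p = 0.0159; adjusted p = 0.204 with an estimated correlation), a call that ended at a mean CPM of at least 5 (adjusted p = 0.158). Mgll, which splits monoglycerides, changed by -3.31 ± 0.11 and the fatty acid carrier Fabp4 by -2.78 ± 0.13. The kinase Sgk1 changed by -2.33 ± 0.11 and the metallothionein Mt1 by -2.55 ± 0.11.

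Of the immune lists described here 4 were called higher with the preset correlation, and none with an estimated one. All 28 markers of T, NK and B cells were higher (28 called when adjusted over the list alone). Their median log2 change was 2.06 (adjusted p = 1.89e-16; adjusted p = 0.118 with an estimated correlation). Cd8b1, a chain of the co-receptor of cytotoxic T cells (chromosome 6, 71322788 to 71337494), rose from 18.9 ± 9.70 to 315 ± 147 CPM. Cd8a changed by 4.58 ± 0.24 and the pore-forming protein gene Prf1 by 3.06 ± 0.16. Of the 23 neutrophil and dendritic cell markers, 21 rose and 1 fell (22 called when adjusted over the list alone; median 2.81; adjusted p = 6.07e-09; adjusted p = 0.054 with an estimated correlation). The integrin Itgax changed by 3.46 ± 0.13 and the dendritic cell chemokine receptor Xcr1 by 3.55 ± 0.17. Antigen presentation genes rose in 12 of 15 (12 called when adjusted over the list alone; adjusted p = 3.28e-13; adjusted p = 0.101 with an estimated correlation). The class II gene H2-Eb1 (chromosome 17, 34305867 to 34316674) went from 214 ± 85.4 to 1880.2 ± 239 CPM and H2-Ab1 from 347 ± 130.3 to 3135 ± 569.9 CPM. Their chaperone Cd74 changed by 2.88 ± 0.10. Macrophage and Kupffer cell markers rose in 22 of 28 and fell in 4 (27 called when adjusted over the list alone; adjusted p = 9.23e-05; adjusted p = 0.349 with an estimated correlation). In that list Tyrobp, an adaptor of myeloid receptors, changed by 2.68 ± 0.18 and the macrophage gene Aif1 rose from 15.98 ± 10.5 to 85.8 ± 17.0 CPM. Mrc1, a mannose receptor that liver endothelium also makes, went the other way, from 1469.8 ± 290.2 to 78.8 ± 23.6 CPM. Chemokines and inflammatory mediators were higher in 20 of 32 and lower in 8 (28 called when adjusted over the list alone). The list was not called (adjusted p = 0.0692, and 0.312 with an estimated correlation). It passed the threshold without replicate 3 of control ZT0, any of the 3 replicates of diet ZT0, replicate 3 of diet ZT6, or replicate 2 or 3 of diet ZT12 (adjusted p from 0.0277 to 0.0494). The chemokines Ccl3 (4.11 ± 0.17) and Ccl4 (3.80 ± 0.17) rose, and the oncostatin M receptor Osmr changed by -3.14 ± 0.11.

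Markers of 2 epithelial cell types also rose. All 20 cholangiocyte markers were higher (20 called when adjusted over the list alone; adjusted p = 2.05e-08; adjusted p = 0.275 with an estimated correlation). Examples are the keratins Krt18 (40.6 ± 10.1 to 207 ± 83.6 CPM) and Krt8 (2.35 ± 0.18) and the tetraspanin Tspan8 (3.29 ± 0.23). Hepatocyte markers rose in 20 of 30 and fell in 4 (24 called when adjusted over the list alone; adjusted p = 0.00206; adjusted p = 0.312 with an estimated correlation), and the list was not called with the hepatocyte score made from it (adjusted p = 0.400). Albumin (Alb) went from 136 ± 31.9 to 515 ± 141 CPM and the plasma protein gene Ahsg changed by 2.73 ± 0.16. Cell cycle genes were called higher as a list (24 higher and 2 lower of 28, 28 called when adjusted over the list alone; adjusted p = 0.000296; adjusted p = 0.312 with an estimated correlation). So were immediate early genes (19 of 25 higher, 20 called when adjusted over the list alone; adjusted p = 8.56e-06; adjusted p = 0.275 with an estimated correlation) and ribosomal proteins (25 of 28, 25 called when adjusted over the list alone; adjusted p = 2.14e-10; adjusted p = 0.244 with an estimated correlation). All 8 measured mitochondrially encoded genes rose (8 called when adjusted over the list alone; adjusted p = 0.000556; adjusted p = 0.332 with an estimated correlation). The immediate early, ribosomal and mitochondrial lists had been set beforehand as measures of sample quality. Examples from the cell cycle list are the replication helicase genes Mcm7 (0.90 ± 0.08) and Mcm3, which went the other way (-0.68 ± 0.06). From the immediate early and mitochondrial lists came the orphan receptors Nr4a1 (2.09 ± 0.14) and Nr4a2 (3.08 ± 0.18), the growth regulator Myc (1.99 ± 0.15) and the respiratory chain gene mt-Nd6 (1.21 ± 0.08). Cholesterol synthesis genes were higher in 13 of 24 and lower in 2 (16 called when adjusted over the list alone; adjusted p = 0.0217; adjusted p = 0.312 with an estimated correlation), among them the sterol enzymes Cyp51 (1.68 ± 0.16) and Fdft1 (0.94 ± 0.08). That list was not called without replicate 2 of control ZT0 (adjusted p = 0.0712), without both control libraries that stand apart (0.0583), at a mean CPM of at least 5 (0.0636) or with the hepatocyte score (0.151).

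**Figure D1:**
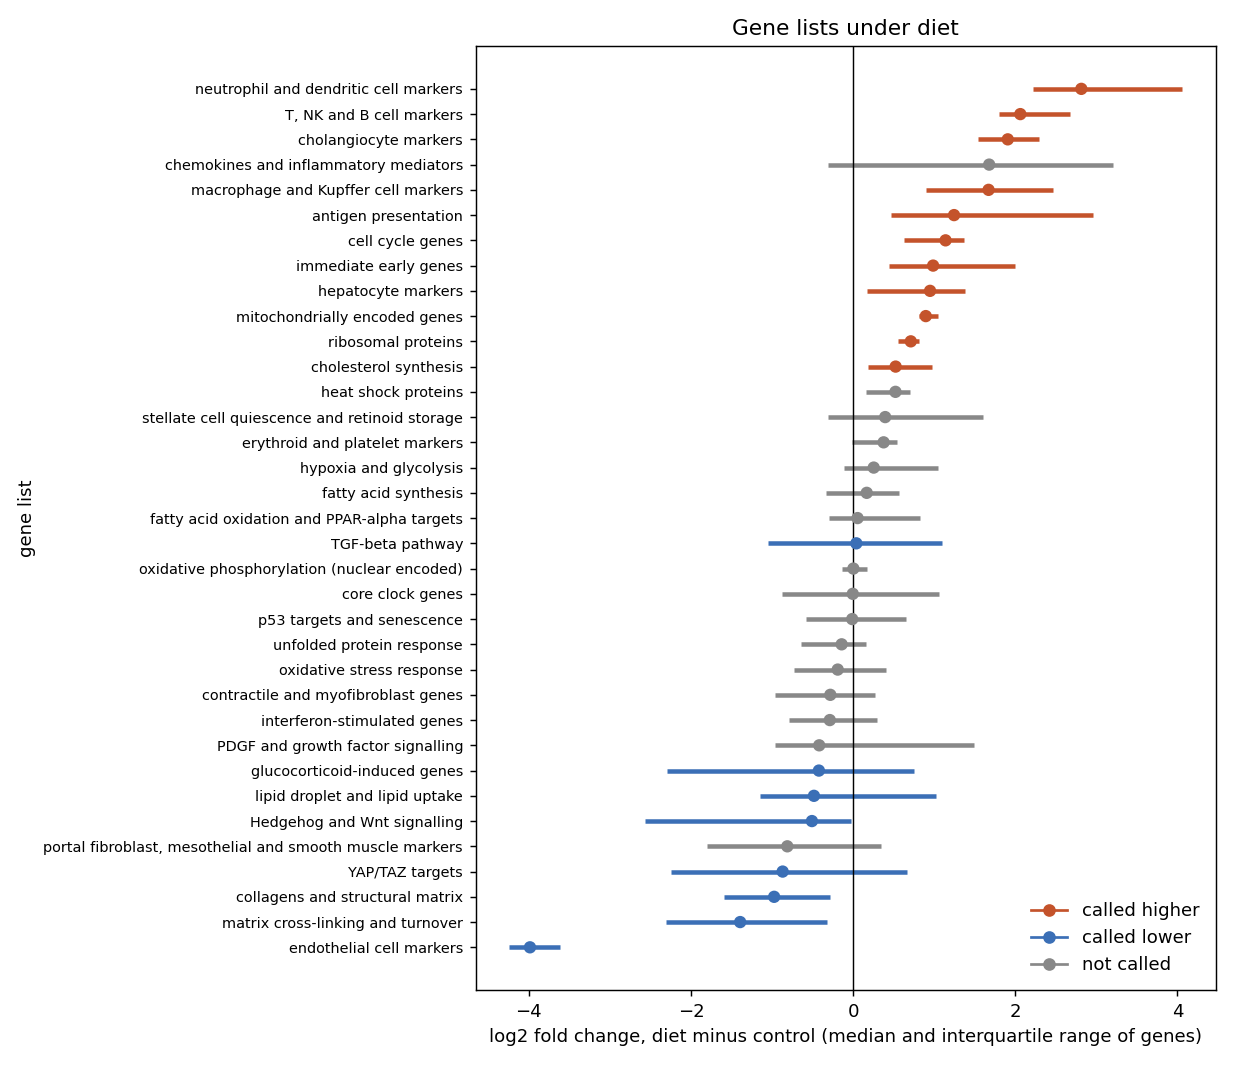
Log2 fold change of diet over control, averaged over the 4 times, for each of the 35 gene lists. Points are the medians and lines the interquartile ranges of each list's genes, coloured by whether the test with a preset correlation called the list. The endothelial list lies alone at a median of -3.98; the TGF-beta list is called lower with a median of 0.04.

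Stellate cell and fibroblast genes were at low levels in both diets. Lrat, which makes retinyl esters, had 1.81 ± 1.11 CPM in control and 1.78 ± 0.908 under diet, and the intermediate filament gene Des 5.82 ± 2.25 and 5.10 ± 2.43. The matrix glycoprotein gene Reln had 2.19 ± 1.47 and 3.08 ± 1.55, Pdgfrb 2.04 ± 1.22 and 2.86 ± 0.978, and smooth muscle actin (Acta2) 5.76 ± 2.38 and 5.28 ± 2.33. None of these 5 was called (adjusted p 0.893, 0.278, 0.185, 0.135 and 0.845). Lrat passed the threshold, as higher, without replicate 2 of control ZT12 (adjusted p = 0.0097), which leaves a library with 0 counts of it at that time. Pdgfrb passed it, as higher, without replicate 1 of control ZT18 (log2 0.84, adjusted p = 0.0167), without both control libraries that stand apart (0.78, 0.0267) and with library size only (0.77, 0.0478). The fibrillar collagens Col1a1 (chromosome 11, 94936224 to 94953042; 12.8 ± 6.05 to 7.20 ± 1.77 CPM, log2 -0.75 ± 0.22), Col1a2 (-0.80 ± 0.25) and Col3a1 (94.0 ± 51.8 to 39.6 ± 16.9 CPM, -1.09 ± 0.27) were lower. The Col1a1 call ended without replicate 1 of control ZT6 (adjusted p = 0.0534), and those of Col1a1 and Col1a2 without the ZT18 libraries (adjusted p 0.0790 and 0.102). With a hepatocyte score as covariate the 3 collagens were not called, at log2 changes of 0.02, -0.54 and 0.15. That score was itself higher under diet, so it takes up part of the diet difference. Timp1 (0.86 ± 0.44, adjusted p = 0.112), Lox (-0.80 ± 0.42, adjusted p = 0.121) and Smad7 (-0.11 ± 0.09, adjusted p = 0.317) were not called, though Lox was lower without replicate 1 of diet ZT12 (-1.24, adjusted p = 0.00748) and Timp1 higher with no filter on low counts (0.89, adjusted p = 0.0492). The growth factor Hgf (-1.74 ± 0.18) and the receptor Tgfbr2 (-1.08 ± 0.07) fell. Tgfb1 (0.40 ± 0.10), the monocyte chemokine Ccl2 (1.26 ± 0.27), the proliferation marker Mki67 (1.11 ± 0.19) and the macrophage marker Adgre1 (1.58 ± 0.21) rose, the first 2 of them not with the hepatocyte score (adjusted p 0.186 and 0.195). The list of stellate cell quiescence and retinoid storage had a median of 0.40 and a test in the other direction that did not pass (adjusted p = 0.57). Contractile genes were not called (median -0.28, adjusted p = 0.813).

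**Figure D2:**
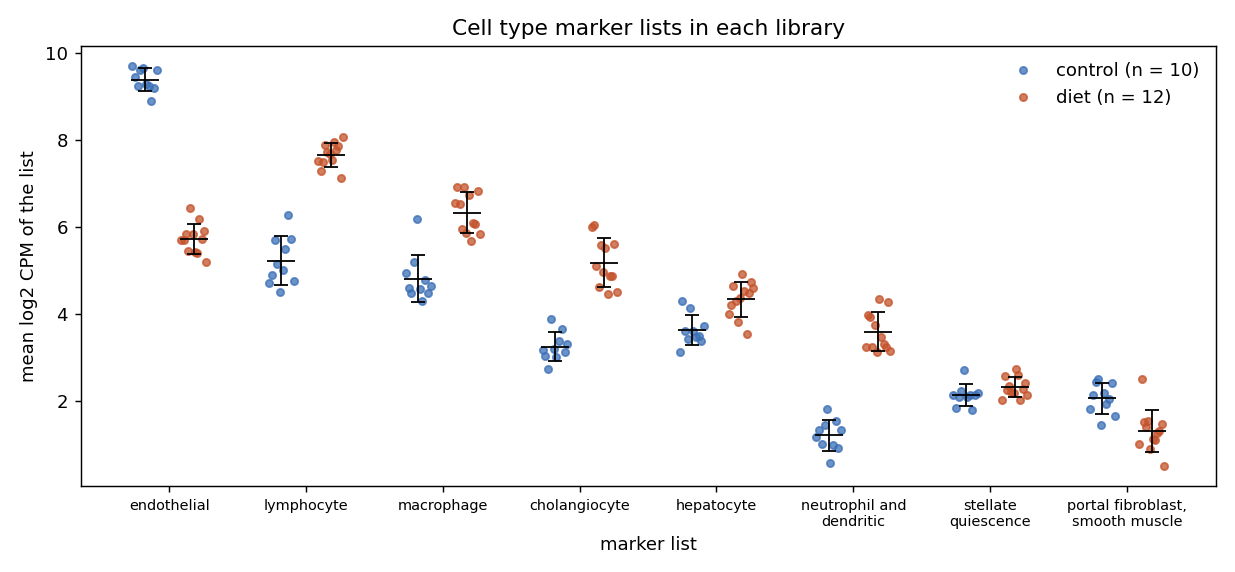
Mean log2 CPM of 8 marker lists in each library; each point is 1 library, the wide dash is the group mean and the bars are the SD (control n = 10, diet n = 12). Endothelial markers average 9.40 in control and 5.73 under diet, lymphocyte markers 5.22 and 7.66, and stellate quiescence genes 2.13 and 2.31.

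The 8 genes that rose most among those at adequate level were the extracellular matrix gene Coch (chromosome 12, 51593341 to 51605771; 7.12 ± 0.65), the NK cell receptor Klra4, and the T-box factor Eomes (6.19 ± 0.28). The others were the granzyme Gzmk (chromosome 13, 113171608 to 113225908; 3.90 ± 2.95 to 222 ± 137 CPM), Mmp12, the immunoglobulin segment Igkv1-88 (5.98 ± 1.06; not called with the hepatocyte score, adjusted p = 0.266), the fucosyltransferase Fut7 and the G protein regulator Rgs16 (5.87 ± 0.37). Klra4 had 0.535 ± 0.773 and 13.03 ± 3.47 CPM and Fut7 0.395 ± 0.448 and 7.91 ± 2.02. Both had groups of control libraries with 0 counts. Receptor segments such as Igkv1-88 and NK receptors such as Klra4 belong to families of near-identical genes, so reads could have been split among them. Lowest against control were the neuronal membrane gene Plppr5 (chromosome 3, 117574836 to 117689507; -6.29 ± 0.35), the neurotrophin Ntf3 (chromosome 6, 126101412 to 126166910; 24.8 ± 7.46 to 0.364 ± 0.296 CPM, -6.20 ± 0.40) and Klhdc8a (-5.25 ± 0.44). After them came the ciliary neurotrophic factor receptor Cntfr (-5.08 ± 0.23), Rnase10 (-5.07 ± 0.43), the lectin Cd209b (-5.02 ± 0.30), Mroh7 (-4.87 ± 0.38) and Exoc3l2 (153 ± 45.2 to 6.28 ± 1.87 CPM).

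By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11748 genes changed: 6161 rose and 5587 fell. By over 2-fold, 3741 rose and 3013 fell. Of the 35 lists, 11 were called higher and 8 lower with a preset correlation, and 1, the endothelial list, with an estimated correlation. With the diet labels permuted within each time, the preset correlation still called a median of 11 lists, though such splits can keep part of the diet difference. The other 16 were not called. With no filter on low counts 24 lists were, among them 6 of these 16: inflammation (adjusted p = 0.00188), heat shock (0.000787), erythroid (0.0105), hypoxia (0.0281), interferon (0.0321, lower) and portal fibroblast genes (0.0345, lower). Besides inflammation, quiescence and contractile genes they were core clock (median -0.00377), PDGF and growth factors (-0.42), interferon-stimulated (-0.29), p53 targets (-0.01), fatty acid synthesis (0.17) and fatty acid oxidation (0.06). The rest were unfolded protein response (-0.14), oxidative stress (-0.19), hypoxia and glycolysis (0.25), oxidative phosphorylation (0.00354), heat shock (0.52), erythroid (0.38) and portal fibroblast genes (-0.81). Scaling by library size alone moved the median of all genes by 0.17 and gave 7635 higher (62.6% against 52.4%) and 4557 lower. It called the heat shock list higher (adjusted p = 0.0450), as did leaving out replicate 1 of control ZT6 (0.0339) or of diet ZT0 (0.0256) and the hepatocyte score (0.0485). Under that scaling the medians of the core clock, p53 and unfolded protein response lists also changed sign, as did those of core clock and p53 with RLE and of core clock and TGF-beta without both control libraries. With a hepatocyte score as covariate, itself higher under diet, 3501 genes were higher and 3686 lower. With an endothelial score, which ran almost parallel to diet (Pearson r = -0.987 over the 22 libraries), edgeR called 0 (879 at an unadjusted p under 0.05).

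At each time taken alone, diet changed 6719 genes at ZT0 (3029 higher, 3690 lower), 6752 at ZT6 (3316 and 3436), 6641 at ZT12 (3205 and 3436) and 6916 at ZT18 (3436 and 3480). With the hepatocyte score as covariate the counts were 3973, 6688, 6026 and 2577. At ZT0 and ZT18 that score was higher in every diet library than in any control library, while at ZT6 and ZT12 the diets overlapped. At all 4 times 1510 genes were higher and 2257 lower, against 9.83 and 13.5 for independent lists. The 4 contrasts share 1 model and its estimates of spread, so independence sets too low a mark. Log2 changes correlated between times at Pearson r of 0.501 to 0.541 across genes, which are not independent replicates. Endothelial, matrix and YAP lists were called lower at all 4 times, and lymphocyte, dendritic cell, macrophage, cholangiocyte, antigen presentation, cell cycle and ribosomal lists higher. With an estimated correlation the endothelial list was called at each time (adjusted p 0.00684, 0.00994, 0.0133 and 0.00896), the clock list at ZT0 (adjusted p = 0.0393) and the dendritic cell list at ZT18 (adjusted p = 0.0107). The other lists called at a time were not called with it.

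The genes named next were among those with the largest changes at a single time. Coch (7.40 ± 0.98), the T cell receptor segment Trbv2 (6.84 ± 1.09) and Igkv1-88 (6.29 ± 1.73) led the increases at ZT0. With the hepatocyte score Igkv1-88 was not called there (2.20, adjusted p = 0.754). Flrt1 (-6.52 ± 0.77) and Klhdc8a (-6.40 ± 0.94) fell there, and Plppr5 went from 657 counts to 1, a ratio of 714 (95% exact counting interval 128 to 28261). At ZT6 Klra4 had 0 counts in both control libraries and 11.6 CPM under diet, at least 144-fold higher against a floor of 3 counts over the group. The checkpoint receptor Tigit rose there (7.22 ± 0.70), and the segment Ighv1-58 went from 1 count to 1229 (ratio 617, interval 111 to 24392). Ntf3 (-7.11 ± 0.86), Klhdc8a (-6.38 ± 0.94) and Cyp26b1, which breaks down retinoic acid, fell; Cyp26b1 changed by -6.23 ± 0.96, or -3.87 without replicate 1 of control ZT6, still called. Fut7 had 0 control counts at ZT12 and was at least 163-fold higher under diet. Coch went from 2 counts to 2238 (ratio 943, interval 261 to 7791) and Eomes changed by 8.77 ± 0.70. Ntf3 (-6.35 ± 0.79) and Cd209b (-6.33 ± 0.66) fell at ZT12, as did the adrenal steroid enzyme gene Cyp11b1 (-6.74 ± 1.73), whose value rested on replicate 2 of control ZT12: without it the change was 1.17 and not called. With the hepatocyte score it was -0.51 and not called (adjusted p = 0.912). At ZT18 Mmp12 rose (8.61 ± 0.68), the myeloid receptor Cd300lb went from 1 count to 944 (ratio 790, interval 142 to 31255) and Igkv2-112 from 2 to 1273 (ratio 533, interval 147 to 4406). Rnase10 (-6.07 ± 0.89), Plppr5 (-5.95 ± 0.64) and Ntf3 (-5.66 ± 0.74) fell. These intervals cover counting error only.

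The second comparison asks which genes differed between times of day in control mice. Endoplasmic reticulum chaperones peaked at ZT6, the middle of the light period. Hspa5, the chaperone BiP (chromosome 2, 34771970 to 34777547), had 1723 ± 258 CPM at ZT6 (SD, n = 2) against 393 ± 19.9 at ZT12 (n = 2) and 501 ± 47.2 at ZT0 (n = 3). It was also high at ZT18 (1103 ± 78.2, n = 3). Hsp90b1, the cofactor gene Sdf2l1, the disulfide isomerase gene Pdia6 and calreticulin (Calr) also peaked at ZT6, with log2 ranges over the 4 times of 2.01, 2.46, 2.05 and 1.74. Of 24 unfolded protein response genes, 17 differed between times (17 when adjusted over the list alone; Fisher's exact test against all other tested genes, adjusted p = 3e-15). With 24 h cosine terms none of these 5 chaperone genes was called in control (adjusted p from 0.240 for Hsp90b1 to 0.795 for Hspa5).

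Core clock genes swung widely in control, 14 of 19 being called (16 when adjusted over the list alone; adjusted p = 4.1e-13). Nr1d1, the repressor REV-ERB alpha (chromosome 11, 98767932 to 98775333), had 403 ± 14.0 CPM at ZT6 and 29.7 ± 3.85 at ZT18, and the transcription factor Dbp (chromosome 7, 45705088 to 45710203) 114 ± 20.7 at ZT12 and 5.16 ± 1.39 at ZT0. Nr1d2, Per2, Per3, Cry2, Tef, Hlf, Ciart and Bhlhe41 were highest at ZT12 and Per1, Cry1 and Nfil3 at ZT18. Arntl, which drives the clock's positive arm, was highest at ZT0 (56.1 ± 12.5 CPM against 6.73 ± 1.68 at ZT12). Nfil3 (adjusted p = 0.0483) lost its call when any of 19 of the 22 libraries was left out, with adjusted p up to 0.288 without replicate 1 of control ZT12. Bhlhe41 lost its call without that same library (adjusted p = 0.0718). Leaving out 1 time ended the calls of Tef (without ZT0, adjusted p = 0.0866), Hlf (without ZT12, 0.132), Bhlhe41 (without ZT12, 0.145, or ZT18, 0.0518) and Nfil3 (without ZT6, ZT12 or ZT18, 0.0582 to 0.656). Nfil3 and Bhlhe41 were also not called with the hepatocyte score (0.172 and 0.0608) or in the control libraries alone (0.275 and 0.0509). Nfil3 was not called with the endothelial score (0.0761), with a replicate block (0.0554) or with cosine terms (0.135) either. Clock, Npas2, Rora and Bhlhe40 were among those not called (adjusted p 0.396, 0.121, 0.446 and 0.111).

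Immediate early genes were highest at ZT18: 19 of 25 were called (24 when adjusted over the list alone; adjusted p = 1.04e-17). Nr4a1 had 720.0 ± 42.5 CPM against 117 ± 47.1 at ZT0, and the log2 ranges were 1.54 for the phosphatase Dusp1 and 1.86 for Fosl2. This list had been set beforehand as a measure of sample quality. Its mean log2 CPM was highest at ZT18 in both diets (7.22 in control and 7.74 under diet). No dates of handling are given, so handling and a daily rhythm cannot be told apart for it. Heat shock genes were called in 12 of 18 (16 over the list alone; adjusted p = 1.15e-10), with Dnaja1 (2.10) and Dnajb1 (2.20) highest at ZT18. Of 24 cholesterol genes 7 were called (12 over the list alone; adjusted p = 0.00103). Srebf2, the regulator of the pathway, and the sterol enzyme Sqle were highest at ZT0, with ranges of 1.24 and 1.76. Markers of other cell types also differed between times. Macrophage markers were called in 16 of 28 (18 over the list alone; adjusted p = 1.77e-12), with Aif1 (1.72) and Tyrobp (1.82) lowest at ZT18. The mean log2 CPM of the macrophage list was 6.18 in replicate 2 of control ZT6 and 4.30 to 5.19 in the other control libraries. Lymphocyte markers were called in 11 of 28 (21 over the list alone; adjusted p = 1.09e-06). Antigen presentation (7 of 15, 9 over the list alone), inflammation (11 of 32, 22), glucocorticoid (7 of 18, 9), dendritic cell (6 of 23, 10) and erythroid genes (5 of 16, 6) were also called more often than other genes (adjusted p 3.8e-05, 4.52e-06, 0.000143, 0.00464 and 0.00464).

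The F test over the 4 times called 1287 genes in control (4609 at an unadjusted p under 0.05), of which 526 were highest at ZT18, 314 at ZT0, 267 at ZT6 and 180 at ZT12. The ZT18 libraries of both diets held less ribosomal RNA than the others, 11.1% ± 1.37 of counts (SD, n = 6) against 19.2% ± 1.91 (n = 16; exact two-sided permutation within diet, p = 3.79e-05, the smallest its 26400 arrangements can give). Without the ZT18 libraries 208 genes differed in control, and Nr4a1, Fosl2 and Dnaja1 were not called (adjusted p 0.463, 0.808 and 0.356). Neither were Aif1 and Tyrobp (0.172 and 0.248), which were also not called in a fit of the control libraries alone (0.111 and 0.127). Tyrobp and Sqle were not called without ZT0 (0.204 and 0.615), nor Tyrobp and Dusp1 with cosine terms (0.125 and 0.108). Fitted alone, the 10 control libraries gave 241 genes; without replicate 2 of control ZT0 the full fit gave 1957 and without replicate 2 of control ZT6 790.

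Under diet the genes with the smallest p were mitochondrially encoded. The cytochrome b gene mt-Cytb (chromosome M, 14145 to 15288) went from 1905 ± 119.8 CPM at ZT6 (n = 3) to 9697 ± 3013 at ZT18 (n = 3), against 2012 ± 494 (n = 2) and 3281 ± 43.1 (n = 3) in control. The complex I genes mt-Nd4, mt-Nd1, mt-Nd2, mt-Nd6 and mt-Nd5 and the oxidase gene mt-Co1 had log2 ranges of 2.02, 1.998, 2.03, 1.60, 1.56 and 1.62, all highest at ZT18 and lowest at ZT6. Of the 8 measured mitochondrial genes 7 were called (8 when adjusted over the list alone; Fisher's exact test, adjusted p = 4.23e-12). Mitochondrial counts took 3.81% ± 0.118 of the diet libraries at ZT6 and 8.84% ± 1.58 at ZT18, the time with the low ribosomal RNA share. Hepatocyte markers moved in parallel under diet, with mean log2 CPM of 4.47 ± 0.16 at ZT0, 3.77 ± 0.23 at ZT6, 4.35 ± 0.14 at ZT12 and 4.76 ± 0.14 at ZT18 (SD, n = 3 each). Of that list 3 of 30 were called (14 over the list alone; adjusted p = 0.0141). Without the ZT6 libraries mt-Co1, mt-Nd2 and mt-Nd5 were not called (adjusted p 0.0707, 0.0765 and 0.165). Also highest at ZT18 were Hspa1a (2.29), the chaperone Hspa5 (0.66) and the erythroid genes Alas2 (1.64) and Hba-a2 (1.41). Without the ZT18 libraries none of these 4 was called (adjusted p 0.152, 0.627, 0.158 and 0.0826), and with the hepatocyte score Alas2 and Hba-a2 were not (0.299 and 0.331). Without ZT6, Alas2 and Hba-a2 were not called (0.352 and 0.530), nor with cosine terms Hspa1a, Hspa5 and Hba-a2 (0.291, 0.902 and 0.103). The endothelial receptor Flt4 was highest at ZT6 (119.6 ± 34.5 CPM), and its call ended without replicate 2 of diet ZT6 (adjusted p = 0.0578). It also ended without ZT6 (0.481) or ZT18 (0.0974), with cosine terms (0.109) and with the hepatocyte score (0.233).

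Of the clock genes, 4 of 19 were called under diet (4 when adjusted over the list alone; adjusted p = 0.000312). These were Dbp (1.62), Nr1d1 (1.41), Per3 (1.35) and Nr1d2 (0.85), the last not without replicate 2 of diet ZT0 (adjusted p = 0.0630). Of the 4, Dbp alone kept its call under each alternative run. Nr1d1 lost it without ZT18 (0.250), without ZT6 (0.121) and with the hepatocyte score (0.179), and Per3 without ZT18 (0.226), without ZT12 (0.0836) and with cosine terms (0.104). Nr1d2 lost it without ZT0 (0.156) or ZT6 (0.0708), with cosine terms (0.249) and with either the hepatocyte (0.0837) or the endothelial score (0.110). Other lists with more calls than other genes were erythroid (5 of 16, 6 over the list alone), immediate early (5 of 25, 13), heat shock (4 of 18, 15), unfolded protein response (4 of 24, 10) and endothelial genes (4 of 28, 23), with adjusted p 9.58e-06, 7.18e-05, 0.00031, 0.000683 and 0.00109. The same held for fatty acid synthesis (3 of 20, 4), lipid droplet (3 of 21, 5), inflammation (3 of 32, 11) and glucocorticoid genes (2 of 18, 4), with adjusted p 0.00535, 0.00551, 0.0154 and 0.0459. In all, 241 genes differed between times under diet (2642 at an unadjusted p under 0.05), 86 of them also called in control against 13.8 for independent lists (Fisher's exact p = 2.16e-45). Both F tests share 1 model, its estimates of spread and the gene levels, and genes move together. This p is thus too small, and the overlap does not by itself measure shared daily rhythms. The counts of 1287 and 241 do not rank the diets: fitted alone, the 12 diet libraries gave 418 genes and the 10 control libraries 241. Without replicate 2 of control ZT0 the diet count was 663, without replicate 2 of diet ZT18 it was 96, and without the ZT18 libraries 24.

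The third comparison asks whether daily swings differed between the diets, and the clock genes answer it most directly. Their mean amplitude, from a 24 h cosine on log2 CPM, was 1.39 (SD 0.67 over genes) in control and 0.45 (0.25) under diet. All 19 measured clock genes had a lower amplitude under diet, and the mean difference was -0.94 (exact two-sided permutation of diet within each time, 40000 arrangements, p = 0.00113; the smallest possible is 2.5e-05). Nr1d1 ranged over 3.76 on the log2 scale in control and 1.41 under diet, and Dbp over 4.46 and 1.62. Per3 ranged over 2.96 and 1.35, Cry2 over 2.78 and 0.68, and Arntl over 3.05 and 0.73. Per1, which glucocorticoids induce, stayed at 96.3 to 110.1 CPM under diet while it went from 27.7 to 72.4 in control. The 4 genes called in both diets peaked earlier under diet by the fitted phase, with a median difference of -0.899 h (-3.42 to -0.761 h), which was not tested. Endothelial markers were at a median of 6.59% of their control CPM in the same diet libraries.

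**Figure D3:**
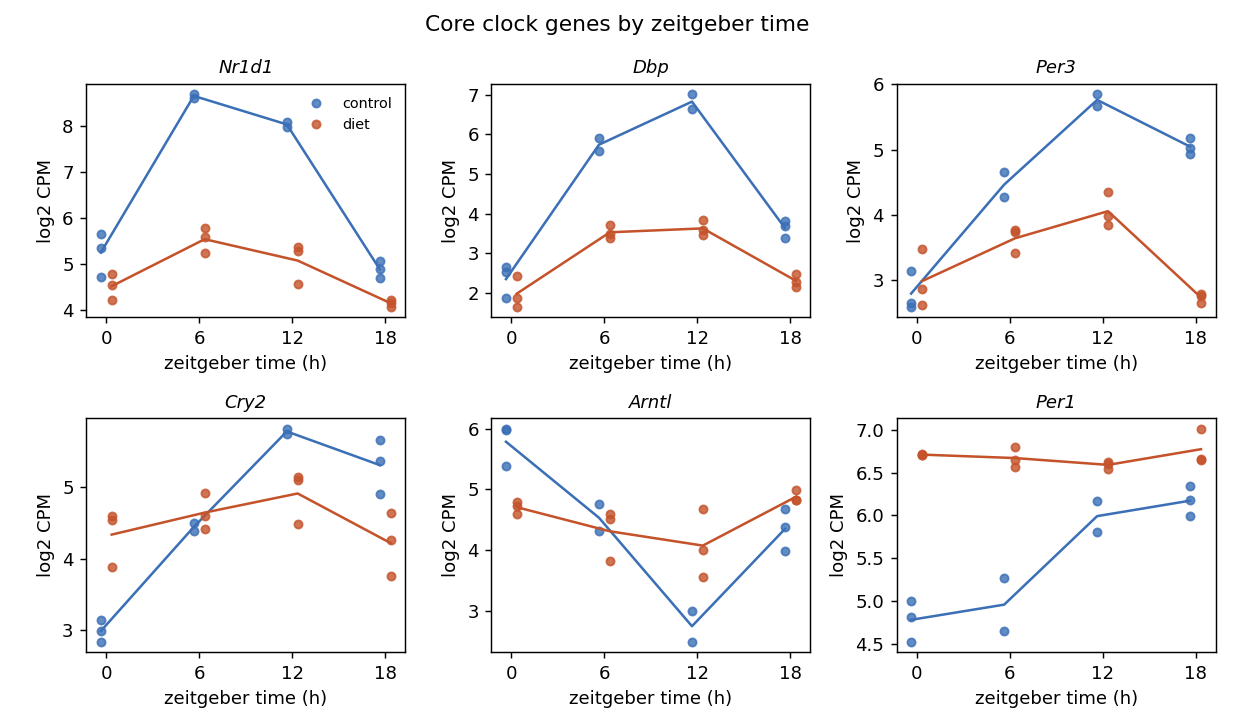
Log2 CPM of 6 core clock genes by zeitgeber time in hours. Points are single libraries and lines join the group means (control n = 3, 2, 2 and 3 at ZT0, 6, 12 and 18; diet n = 3 at each). Nr1d1 spans a log2 range of 3.76 in control and 1.41 under diet.

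Gene by gene, the diet effect differed between times for 11 of 19 clock genes (14 when adjusted over the list alone; Fisher's exact test, adjusted p = 6.06e-17). They were Nr1d1, Nr1d2, Dbp, Per3, Cry2, Per1, Tef, Arntl, Ciart, Cry1 and Bhlhe41. Of these, Bhlhe41 lost its call when any of 14 of the 22 libraries was left out (adjusted p up to 0.0908), Cry1 with any of 9 (up to 0.0632) and Arntl without replicate 2 of diet ZT0 (0.0524). Leaving out ZT0 ended the calls of Arntl, Cry2, Nr1d2 and Tef (adjusted p 0.152, 0.121, 0.139 and 0.497), and leaving out ZT12 those of Ciart and Bhlhe41 (0.137 and 0.242). Leaving out ZT18 ended those of Per1, Per3, Arntl, Ciart, Cry1 and Bhlhe41 (0.0552, 0.0872, 0.0615, 0.0596, 0.201 and 0.113), and leaving out ZT6 those of Cry1 and Bhlhe41 (0.105 and 0.0547). With a replicate block Cry1 and Bhlhe41 were not called (0.0563 each), nor was Bhlhe41 with the hepatocyte (0.198) or endothelial score (0.0527). Of the 11, Nr1d1 and Dbp kept their calls under each alternative run. Unfolded protein response genes were called in 13 of 24 (18 over the list alone; adjusted p = 3.22e-19). Hspa5 (adjusted p = 5.74e-07) had a log2 range of 2.13 in control and 0.66 under diet, and at ZT6 1723 ± 258 and 789.6 ± 32.5 CPM. Hsp90b1, Sdf2l1, Pdia6 and Calr ranged over 0.51, 0.74, 0.62 and 0.50 under diet. With 24 h cosine terms none of these 5 chaperone genes was called (adjusted p from 0.356 for Hsp90b1 to 0.621 for Hspa5). Without the ZT6 libraries Hspa5 was called and the other 4 were not (adjusted p from 0.321 for Sdf2l1 to 0.648 for Calr). Also among the 8 smallest p were the kinase gene Pim3 (362 ± 23.4 CPM in control and 78.4 ± 10.1 under diet at ZT6) and the membrane protein gene Tmem221 (22.6 CPM at ZT0 and 2.53 at ZT18 in control, 42.0 and 47.1 under diet). Pim3 was not called without ZT6 (adjusted p = 0.0535) or with cosine terms (0.0912), nor Tmem221 without ZT18 (0.185) or with cosine terms (0.141). Srebf2 ranged over 0.18 under diet, and 4 of 24 cholesterol genes were called (5 over the list alone; adjusted p = 0.000439). Mitochondrial genes were called in 5 of 8 (7 over the list alone; adjusted p = 4.95e-08), with the larger range under diet. The genes mt-Nd4 and mt-Nd2 lost their calls without replicate 1 of control ZT6 (adjusted p 0.0505 and 0.0547), with the hepatocyte score (0.0623 and 0.0847), without ZT18 (0.102 and 0.0615) and without ZT6 (0.359 and 0.622). Also called more often than other genes were heat shock (5 of 18, 10 over the list alone), neutrophil and dendritic cell (4 of 23, 10), hepatocyte (4 of 30, 13) and immediate early genes (3 of 25, 15), with adjusted p 5.26e-06, 0.000439, 0.000928 and 0.0075. The same held for matrix turnover (3 of 28, 3), glucocorticoid (2 of 18, 6), fatty acid synthesis (2 of 20, 2) and cholangiocyte genes (2 of 20, 11), with adjusted p 0.0093, 0.0443, 0.0453 and 0.0453.

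**Figure D4:**
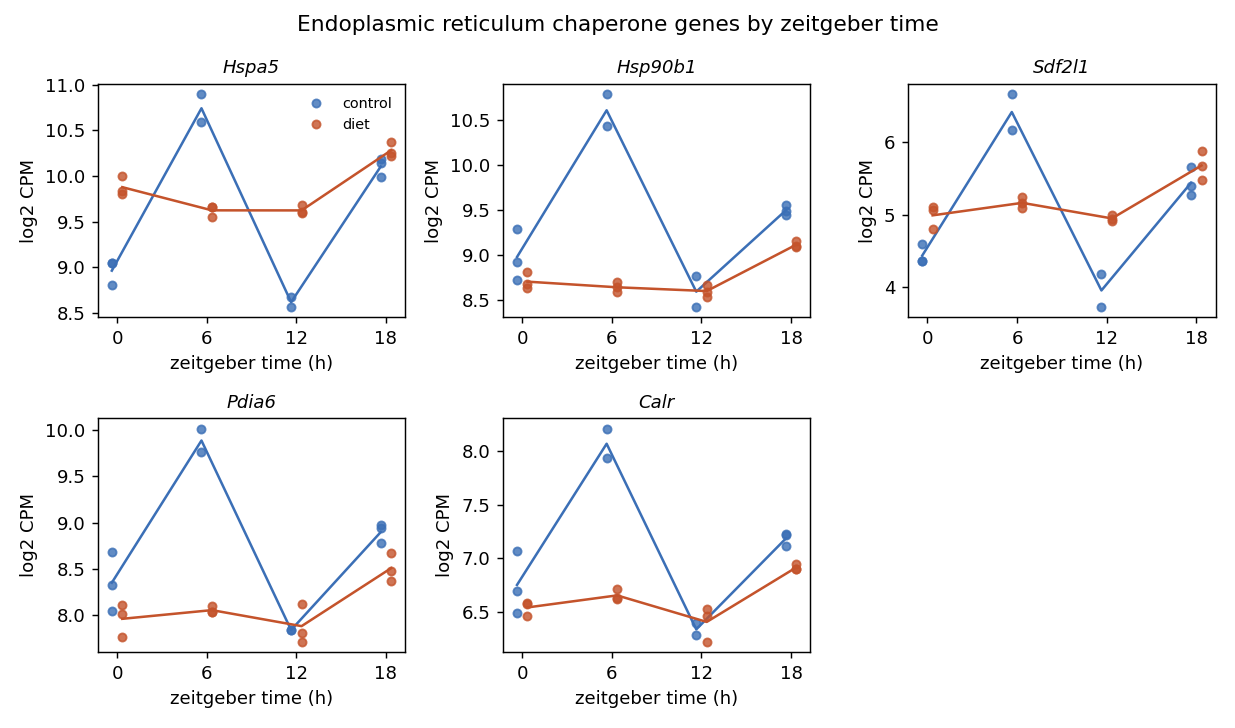
Log2 CPM of 5 endoplasmic reticulum chaperone genes by zeitgeber time in hours. Points are single libraries and lines join the group means (control n = 3, 2, 2 and 3 at ZT0, 6, 12 and 18; diet n = 3 at each). Both ZT6 control libraries lie above all other libraries for each gene.

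In all, the diet effect differed between times for 215 genes (3241 at an unadjusted p under 0.05), of which 180 had the larger range in control. Over all tested genes 14615 of 22409 (65.2%) had the larger range in control, where 2 of the 4 means rest on 2 libraries and so vary more. The count was 1086 without replicate 2 of control ZT0, 76 without replicate 2 of diet ZT0, 34 without the ZT18 libraries and 57 without those of ZT6.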

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

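The tests of scaling, vessel markers, endothelial share, the 2 control libraries, dilution, a single ZT6 library and handling were chosen after the results were seen; those of plasma cells and of other splits were written before.

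A diet effect that differed between times, by the interaction test, marks these genes for a second look. Clock genes with their adjusted p were Nr1d1 (0.000462), Nr1d2 (0.000542), Dbp (0.000851), Per3 (0.00139), Cry2 (0.00423), Per1 (0.00569), Tef (0.00904), Arntl (0.0195), Ciart (0.0235), Cry1 (0.0346) and Bhlhe41 (0.0379), and the mean amplitude differed by -0.94 on the log2 scale. Chaperones were Hspa5 (5.74e-07), Hsp90b1 (0.000106), Sdf2l1 (0.000462), Pdia6 (0.000851) and Calr (0.00172). Cholesterol genes were Srebf2 (0.00195) and Fdft1 (0.0369), and mitochondrial genes mt-Nd4 (0.0154), mt-Nd2 (0.0183), mt-Cytb (0.0261), mt-Nd1 (0.0329) and mt-Nd5 (0.0431). Immune genes were Itgax (0.00904), Eomes (0.0294), Klra4 (0.0335), Cd300lb (0.0346) and Mmp12 (0.04999), and the rest Pim3 (0.000809), Tmem221 (0.000851), Nr4a2 (0.0235) and Mt1 (0.0453).

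Endothelial markers fell and lymphocyte markers rose under diet. Scaling does not account for it, since the endothelial median stayed at -3.80 or below under 3 scalings. A loss of sinusoidal identity alone is argued against, since markers shared by all vessels fell by a median of 3.93 (interquartile range -4.22 to -3.84). A lower endothelial share alone would raise all other cell types alike, but the lymphocyte median exceeded that of 14 core stellate cell genes by 2.15, with ranges of 1.80 to 2.68 and -0.79 to 1.02 that do not overlap. The lists of vessel and core stellate cell genes were made after several of their genes had been seen to change. Neither comparison is thus an independent test, and stellate cell genes were at low levels. A change in the shares of several cell types may remain, arising in the liver or in the isolation, which the labels do not describe. A direct effect of diet on each cell type was not tested.

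Clock gene amplitude was lower under diet. The 2 control libraries that stand apart do not account for it, since without both the difference was -0.96 (exact permutation, p = 0.0038). Dilution of an endothelial rhythm by cells without one could lower it: the median swing in CPM of the 14 genes called in control was 22.6% of that in control (interquartile range 12.4 to 29.1%), and endothelial markers were at 6.59% (5.49 to 8.53%). The swing is the highest minus the lowest group mean and never below 0, so noise raises it, and dilution and a weaker clock in each cell cannot be told apart from mixed cells. Diet as the biological cause stays open, untested.

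Endoplasmic reticulum chaperones peaked at ZT6 in control. The median excess at ZT6 of the 13 genes with a diet by time effect was 1.20 on the log2 scale and 1.17 or more without either ZT6 library, and B and plasma cell genes, whose cells are rich in these chaperones, were higher by 0.0305, so neither a single library nor plasma cells account for it. The 17 genes called in control had a median excess at ZT6 of 1.11 in control and -0.0483 under diet (interquartile range -0.09 to 0.02). This argues against handling shared by the ZT6 libraries of both diets, if it acts on all cells alike. The 17 genes were chosen by their control values, and endothelial markers were at 6.59% of control CPM under diet. Handling that acts on endothelial cells could thus be diluted under diet, and the values cannot decide on it. Handling of the ZT6 control libraries alone cannot be told apart from a daily rhythm, since no dates are given and their ribosomal RNA share (17.1%) decides nothing. A feeding rhythm that differs between the diets would be a biological cause, which was not tested.

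Other splits were drawn by permuting labels, 100 in all with the real one. With diet permuted within time, 1 of 100 gave as many genes higher (the real 6161, the highest other 3111). Again 1 of 100 gave as many lower (5587 and 3168). Both counts are thus rare among random splits of these libraries. No label says that each library came from its own animal, so chance between animals cannot be excluded. For the lists, 6 of 100 gave as many as the real 19 (highest other 19), so chance cannot be excluded for the number of lists called with a preset correlation. The other splits called a median of 11 lists. They can keep part of the diet difference, since groups of 3 libraries cannot be balanced for diet. The number alone thus does not measure how lenient a preset correlation is. With an estimated correlation 1 list was called. With times permuted within each diet, 1 of 100 gave as many in control (1287, highest other 471) and under diet (241 and 28). These counts too are rare among random splits of these libraries. In the interaction 1 of 100 gave as many (215 and 72). Permuting times also removes the time differences that the diets share, so it cannot decide on chance for the interaction alone. At ZT0 (6719 genes) and at ZT18 (6916), 1 of 10 splits was the real one and the highest other gave 0 in both, but 10 splits are too few for a share under 0.05.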

How the results depend on the processing

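Leaving out 2 control libraries, each time, or fitting an endothelial score was chosen after the results were seen; the other alternatives were planned. The clock amplitude difference kept its sign and its side of the threshold under every alternative run, from -0.990 to -0.900 with single libraries left out (p from 0.00035 to 0.00365) and from -0.960 to -0.864 otherwise. The amplitude was not computed with the hepatocyte or endothelial score or with a time left out. Nor was it computed with DESeq2, with cosine terms or in fits of only the groups compared. The counts of genes changed by diet at each time stayed within 1.5 times under each alternative except the hepatocyte score, which gave 3973 at ZT0 and 2577 at ZT18, as well as 3501 higher, 3686 lower, 84 between times under diet and 126 in the interaction. It also turned Col1a1 to 0.0194 and Col3a1 to 0.15 (adjusted p 1 and 0.862). That score itself differed with diet at ZT0 (mean log2 CPM 3.54 ± 0.15 in control and 4.47 ± 0.16 under diet) and ZT18 (3.48 ± 0.12 and 4.76 ± 0.14). At ZT6 (3.63 ± 0.71 and 3.77 ± 0.23) and ZT12 (3.95 ± 0.48 and 4.35 ± 0.14) the libraries overlapped. Calls lost with it thus cannot tell hepatocyte transcripts from diet itself. By edgeR an endothelial score left 0 genes higher and 0 lower (879 at an unadjusted p under 0.05), by its construction, since 97.5% of its variance lies between the diets. With an estimated correlation 1 list was called. Without both control libraries that stand apart, 11362 of the 11748 genes changed by diet, 1084 of the 1287 that differ between times in control and 211 of the 215 interaction genes kept their calls.

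Counts of genes that differ between times moved widely, and the cause was not tested where none is given. In control, under diet and in the interaction they were 709, 24 and 40 with cosine terms, which miss other shapes; 3103, 1128 and 1464 with DESeq2; and 2866, 1500 and 2085 with no filter. A mean CPM of at least 5 gave 425 under diet and 388 in the interaction, and library size only 561 under diet. Fits of only the groups compared gave 241 in control and 418 under diet. Without both control libraries 632 differed under diet and 1004 in the interaction. Without ZT18 the counts were 208, 24 and 34, and without ZT6 602, 84 and 57; without ZT12 421 under diet and 336 in the interaction; and without ZT0 589 in the interaction. Single libraries left out gave 790 to 1957 in control (lowest without replicate 2 of control ZT6), 96 to 663 under diet (lowest without replicate 2 of diet ZT18) and 76 to 1086 in the interaction (lowest without replicate 2 of diet ZT0). All 3 were highest without replicate 2 of control ZT0. The log2 change of Cyp11b1 at ZT12 ranged from -7.72 (without replicate 1 of control ZT12) to 1.17 (without replicate 2). A group left with 1 library was assumed to vary like the others.

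The replicate numbers are shared by the groups but do not pair the libraries: deviations of same-numbered libraries correlated at a mean of -0.005, 2 of 71 pairs passed 0.1, and 4 of 22 libraries were closest to their own number. With the number as a block (replicate block) 123 genes were called in the interaction and the amplitude difference was -0.885. Stellate cell markers at 1.78 to 5.82 CPM carry standard errors of 0.21 to 0.45. Whether these come from depth or from spread between libraries was not tested.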

Other observations

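The marker lists and adrenal genes described here were chosen after the results were seen.

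Marker transcripts of immune cell subsets were higher under diet. T cell checkpoint and regulatory genes (Tigit, Pdcd1, Lag3, Ctla4 and others) were higher in 9 of 9, with a median log2 change of 4.11. NK and cytotoxic genes were higher in 9 of 9 (median 3.06), B and plasma cell genes in 8 of 8 (2.20) and T cell genes in 12 of 12 (1.92). Sinusoidal endothelial genes fell in 10 of 10 (-4.25), and endothelial genes shared by all vessels in 12 of 12 (-3.93). Of 14 core stellate cell genes 2 rose and 6 fell (-0.09). Several of these genes had been seen to change before the lists were made, so no p-value of these lists is given. The lists of all vessels, core stellate cells and B and plasma cells served above to weigh explanations by their values only. Some also stand in the lymphocyte and endothelial lists.

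Genes of steroid synthesis in the adrenal cortex appeared in 5 of the 22 libraries: all 3 of control ZT18, replicate 2 of control ZT12 and replicate 1 of diet ZT18. Hsd3b1, which makes progesterone, had 79.2 to 252 CPM in these and at most 4.79 in the other 17. Cyp21a1 had 39.8 to 137 CPM against at most 2.42, Cyp11b1, which makes corticosterone, 18.2 to 66.3 against at most 0.921, and Akr1b7 8.12 to 38.3 against at most 0.335. The same 5 libraries passed 5 CPM for all 4 genes, and 4 of the 5 were taken at ZT18. Whether adrenal tissue was carried over was not tested, nor whether these libraries bear on the genes highest at ZT18 in control or on the calls at ZT18 and in the interaction.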
